A study of Homo sapiens with 6 samples.

How the data were processed

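Polyadenylated RNA from 6 cultures of the breast cancer cell line MDA-MB-468 was sequenced, 3 labelled as parental and 3 labelled as GPR52 KO. Per the labels' protocols, total RNA was extracted by Trizol lysis with a column kit and made into libraries with a poly(A) isolation module and a directional kit that keeps strand. The authors deposited a table of raw counts per gene symbol and a table of FPKM values, each with 1 column per sample. The deposited counts are whole numbers that sum to a different total in each library, and the deposited FPKM values are decimals scaled by transcript length and library size. The submitters' processing notes name STAR 2.4.0f1, SAMtools 0.1.19, Cufflinks 2.0.2 and the genome build hg19, without saying which step each served. The annotation, the counting program, its strand setting and any filter are not given in the sources used here. The name of each deposited table holds the word unique, which no other source used here explains. If reads with several placements were left out, genes with near-identical copies are undercounted, and overlapping or antisense genes cannot be told apart where the counting ignored strand.

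Samples were grouped by the genotype label. The parental samples were wells of 1 culture plate and the others 3 edited populations, so no pairing exists between the groups. The labels do not say what the edited populations' titles mean or whether the populations are clones, pools or subcultures of each other, and their replicate numbers follow the order of deposition only. The tests treat the 6 libraries as independent. No non-targeting control was analysed here, and editing, selection and time in culture go together with the label. Total counts of 25637794 to 31692454 per library make 1 count worth 0.0321 to 0.0397 CPM. A fold change against a group with 0 counts was computed against a floor of 3 counts over the group, and a group with 1 to 3 counts was given as a ratio of counts scaled to library size, with an exact 95% binomial interval. Tested genes held 99.9% of the counts in each library.

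Differential expression was computed from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), normalised by TMM, and tested with the quasi-likelihood F test in its current (not legacy) form, with all 6 libraries and no covariate. Adjusted p-values are Benjamini-Hochberg values over 17420 genes, and the threshold was 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Mean and SD per group are of CPM with TMM library sizes. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, adjusted over 32 lists. Chromosomes and windows of 20 Mb with at least 20 tested genes were tested in the same way. The deposited tables give no positions. Gene order was therefore taken from a GENCODE annotation of GRCh38, a later build than the authors' hg19, and used for neighbourhood and names of bordering genes only, so no coordinates are given. Positions were found for 14892 (85.5%) of the tested genes.

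Genes named in the text follow a rule fixed before the data were examined, as were the 34 lists, the tests and most alternatives. The rule took GPR52 and RABGAP1L, then the 10 largest rises and 10 largest falls among genes with an adjusted p under the threshold, an average log2 CPM of at least 2 and no overlap between groups, passing over uncharacterised loci, and then up to 4 changed members of each list with the smallest p. A few further list members (ATF4, HMGCS1, CDH1, VIM, ZEB1, EGFR, FOS, NR4A1, DUSP6 and MKI67) were named after their values were seen, because a reader would look for them. One of the 10 largest falls, 1 of the 3 called lists, 1 member of another list and 1 window are not reported here.

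Alternatives were other normalisations (DESeq2 size factors, upper quartile, library totals), other filters (none, or 10 CPM in 3 samples), DESeq2 1.42.0, limma voom, the legacy robust quasi-likelihood fit, limma on log2(FPKM + 1) and log2(FPKM + 0.1), counts thinned to the smallest library, a test against a 1.5-fold change, windows of 10 Mb, estimated correlations and fry for the lists, and leaving out each library in turn. Chosen after seeing the data were a fit relative to neighbours, in which the median log2 fold change of a gene's window was added as an offset to the KO-labelled libraries (for lists, taken off log2 CPM, with a preset and with an estimated correlation), a correction for GC content and transcript length, leaving out parental-labelled 1 together with KO-labelled 3, and all thresholds for switched genes. The edgeR steps were tested on simulated counts for 16771 genes, with the means of the parental-labelled libraries and the library sizes of this comparison. Both groups were drawn with the same dispersion per gene. The real KO-labelled libraries varied more (ratio of median SDs 2.18), so the shares below do not cover unequal spread. Only 200 genes were changed in the simulation, far fewer than were called here, so the cut on p was stricter. Of genes changed 1.5-fold 33.9% were called, of those changed 2-fold 72.1% and of those changed 4-fold 95.2%, and 3.88% of calls were unchanged genes. In the list test 0 of 200 random lists were called, and a planted list was. The simulated genes were drawn independently of each other, so this cannot show how the list test does where members vary together. In the real libraries the estimated correlation was 0.268 for the list of ATF4 and amino acid stress genes. Figures were drawn with matplotlib 3.10.9.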

Results

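RNA sequencing was carried out on 6 cultures of MDA-MB-468, an established triple-negative, basal-like breast cancer cell line with high EGFR expression. The parental group held 3 libraries, grown in parallel wells of 1 plate. The other group held 3 libraries labelled GPR52 KO, from populations that the submitters edited with CRISPR-Cas9 and 1 guide RNA against GPR52, an orphan G protein-coupled receptor that signals through cAMP. The series description states that insertions or deletions at the target were seen by Sanger sequencing. Total gene counts were 30629724, 25637794 and 31692454 in the libraries labelled parental 1 to 3, and 25983764, 27956600 and 27742162 in those labelled GPR52 KO 1 to 3. One count corresponded to between 0.0321 and 0.0397 CPM (counts scaled to library size), and 17420 of 31122 genes had enough counts to be tested. Throughout, ± gives the SD over the 3 libraries of a group, and intervals and floors cover counting error only. The parental libraries were wells of 1 line, so p-values measure a spread that may be technical on that side. The labels do not say whether the edited populations are clones or pools or how they are related, so their 3 libraries may not be independent either.

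The targeted gene was examined first, because it checks the labels. GPR52, which lies on chromosome 1 within an intron of RABGAP1L on the same strand, was nearly absent from the libraries labelled parental and present in every library labelled GPR52 KO. Its counts were 9, 1 and 0 in the libraries labelled parental and 645, 694 and 724 in those labelled GPR52 KO. This corresponded to 0.112 ± 0.161 CPM against 24.9 ± 0.833 CPM (SD, n = 3 each), a log2 fold change of 7.70 (SE 0.35) with an adjusted p of 4.1e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg). The host gene RABGAP1L, a RAB GTPase-activating protein, went from 41.9 ± 1.81 to 27.6 ± 1.72 CPM, with a log2 fold change of -0.60 (SE 0.08) and an adjusted p of 8.3e-04 in the same edgeR test. The fitted GPR52 fold change rests on few parental counts and was 10.12 without the library labelled parental 1, which held 9 of the 10 counts, and 7.07 without parental 3. The authors' FPKM values went the same way for GPR52, with 0.139, 0.0185 and 0 against 12.0, 12.3 and 12.5. RABGAP1L went from 13.1 ± 1.54 to 9.78 ± 1.41 FPKM (SD, n = 3 each), the same direction and with no overlap between the groups, but the limma test on FPKM did not reach the threshold, with an adjusted p of 0.0566 for log2(FPKM + 1) and 0.0537 for log2(FPKM + 0.1). An edit that shifts the reading frame need not lower a transcript, but a gain of the transcript goes against the label as a loss of GPR52 expression. The groups are therefore called KO-labelled and parental-labelled, and every direction below is that of the KO-labelled libraries relative to the parental-labelled ones, whatever the state of GPR52 in them.

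**Figure D1:**
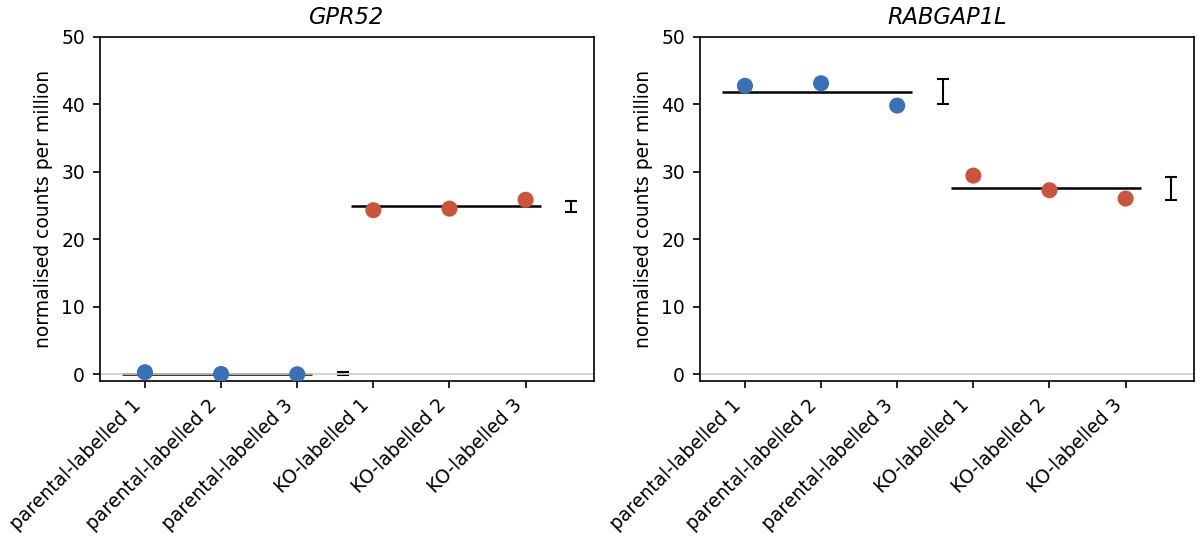
Normalised CPM of GPR52 (left) and RABGAP1L (right) in each of the 6 libraries (points), with the group mean (line) and SD over 3 libraries (bar beside it). GPR52 averaged 0.112 CPM in the parental-labelled and 24.9 CPM in the KO-labelled libraries, and RABGAP1L 41.9 and 27.6 CPM.

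The comparison of KO-labelled with parental-labelled libraries was designed to address what loss of GPR52 does to gene expression in these cells, in libraries where the GPR52 transcript was higher under the KO label. GSTP1, a glutathione transferase, rose from 0.189 ± 0.237 to 78.2 ± 4.24 CPM (SD, n = 3 each), and FAR1, which reduces fatty acyl-CoA to alcohols in ether lipid synthesis, rose from 0.330 ± 0.333 to 53.5 ± 2.68 CPM. In the opposite direction, the membrane aminopeptidase ANPEP fell from 349 ± 7.41 to 2.04 ± 1.92 CPM, and the lactate dehydrogenase subunit LDHB from 29 ± 0.901 to 0.627 ± 1.06 CPM. The log2 fold changes of GSTP1 and FAR1 were 8.61 (SE 0.31) and 7.26 (SE 0.32), and 10.40 and 8.35 without parental-labelled 1, which held most of their few parental counts. Those of ANPEP and LDHB were -7.43 (SE 0.47) and -5.57 (SE 0.62), and -8.48 and -10.36 without KO-labelled 1, which held 49 of the 50 LDHB counts of its group, and LDHB was at -4.98 without KO-labelled 3. MAGED1, an X-linked member of the melanoma antigen family, went from 45.8 ± 1.30 CPM to 0 counts in all 3 KO-labelled libraries, at least 1267-fold lower when 3 counts over the group are taken as the floor. In all, 7105 genes changed, 40.8% of those tested, of which 3661 were higher and 3444 lower in KO-labelled libraries.

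Further genes among the 10 largest rises were the RNA-binding protein IGF2BP1, with 0.0880 ± 0.152 to 28.7 ± 4.38 CPM and a log2 fold change of 8.21 (SE 0.41), FAM83E at 7.42 (SE 0.26), and TNFRSF10D, a decoy receptor for the death ligand TRAIL, at 7.41 (SE 0.34). Other genes had 3 or fewer counts in the parental-labelled group, so their ratios are given with counting intervals. By that measure PDZD4 was higher 1361-fold (95% counting interval 376 to 11244), the collagen gene COL5A1 549-fold (95% counting interval 152 to 4537), C11orf53 364-fold (95% counting interval 100.5 to 3014) and SDR16C5 346-fold (95% counting interval 118 to 1679). GPR52, GSTP1 and FAR1 were the remaining genes of the 10. The sizes rest on few parental counts. Without parental-labelled 1 the fitted log2 fold changes were 12.64 for IGF2BP1, all of whose parental counts were in that library, 8.19 for FAM83E and 8.29 for TNFRSF10D. They were 11.46 for COL5A1 and 11.39 for SDR16C5, in place of 8.85 and 8.27. Without parental-labelled 3 IGF2BP1 was at 7.59 and SDR16C5 at 7.68, without parental-labelled 2 PDZD4 at 12.82 in place of 10.16, and without KO-labelled 1 C11orf53 at 7.59 in place of 8.27.

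Among the 10 largest falls, SCGB2A2, which encodes the secreted mammary protein mammaglobin-A, went from 39.6 ± 1.29 to 0.0369 ± 0.0377 CPM and was 1095-fold (95% counting interval 374 to 5313) lower. The potassium-chloride cotransporter SLC12A7 was 538-fold (95% counting interval 148 to 4445) lower. MAP7D2 had a log2 fold change of -7.25 (SE 0.29), and the homeobox gene EN1 one of -6.11 (SE 0.24). The mitochondrial carrier SLC25A30 and the fatty acid elongase ELOVL6 had log2 fold changes of -5.22 (SE 0.47) and -5.10 (SE 0.40). Without KO-labelled 1 SLC25A30 was at -7.32 and SCGB2A2 at -10.81 in place of -9.93, and ELOVL6 was at -5.88 without KO-labelled 2 and -4.51 without KO-labelled 3. With all 6 libraries, adjusted p-values of the 19 genes named from both groups of 10 ranged from 1.8e-08 to 3.1e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg). A p under the threshold and no overlap between groups were conditions of the choice, so neither adds support.

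**Figure D2:**
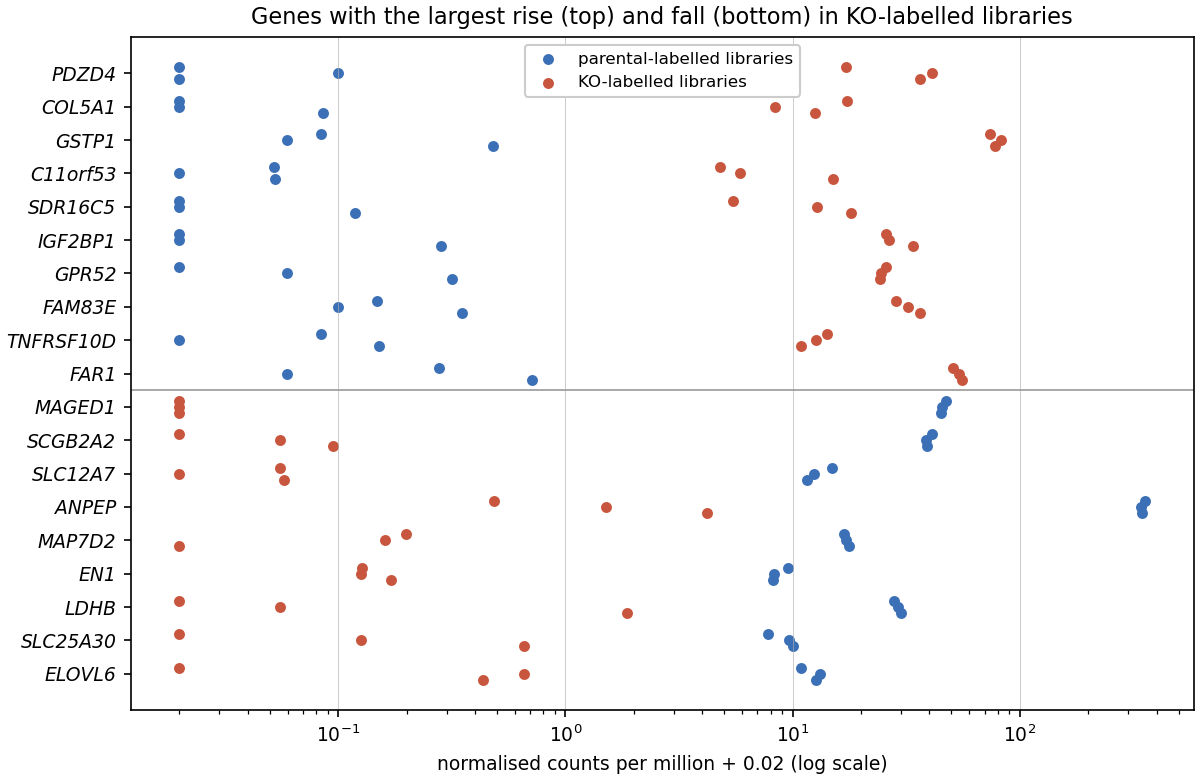
Normalised CPM in each library (points, 0.02 added so that 0 can be drawn on the log axis) for the 10 genes with the largest rise and 9 of the 10 with the largest fall. No overlap between parental-labelled and KO-labelled libraries was a condition for choosing these 19 genes. GSTP1 averaged 0.189 against 78.2 CPM and ANPEP 349 against 2.04 CPM.

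Of the changed genes, 1162 were higher and 938 lower by more than 2-fold, and 234 and 123 by more than 8-fold. The 2 groups did not overlap for 9479 genes (54.4%), where chance gives 10% for 3 against 3 if all libraries are exchangeable. Since libraries within a group may not be independent here, 10% is not a firm chance level. Libraries of the parental-labelled group resembled each other more than the KO-labelled ones did. Pearson correlations across genes of log2 CPM were 0.995 for each parental-labelled pair. They were 0.991 for KO-labelled 1 and 2, 0.981 for 1 and 3, and 0.984 for 2 and 3, against 0.944 to 0.948 between groups. The median SD of log2 CPM was 0.09 in the parental-labelled and 0.19 in the KO-labelled group, a ratio of 2.18, and 76.3% of genes were wider in the latter. The difference on the log2 scale was 1.12, and 0.40 without KO-labelled 3 and 1.82 without parental-labelled 3. No library pair agreed within sampling noise, the lowest chi-square per gene being 3.08. KO-labelled 3 stood apart on the second principal component, which held 11.0% of the variance, while the first held 78.9% and separated the groups. The number of changed genes was 9367 without KO-labelled 3, and 1922 when tested against a 1.5-fold change (glmTreat).

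Gene lists fixed before the data were examined were then compared, 34 in all, of which 32 had enough tested members for a competitive test (camera). Values given for a gene without a unit are log2 fold changes with their SE, camera values are p-values adjusted over the 32 lists, and the count adjusted over the list alone is the number of members that changed in either direction. In the list of the amino acid stress response driven by ATF4, 16 of 26 tested members were higher, 1 lower and 9 not called, 19 changed when adjusted over the list alone, and the median log2 fold change was 0.51 (camera adjusted p = 3.0e-04 with the preset correlation of 0.01, and 0.916 with an estimated one). The cystine transporter SLC7A11 rose from 12.6 ± 1.12 to 37.9 ± 1.91 CPM with a log2 fold change of 1.59 (SE 0.10), the serine synthesis enzyme PHGDH had one of 0.82 (SE 0.06), the glycyl-tRNA synthetase GARS 0.82 (SE 0.07) and the mitochondrial serine hydroxymethyltransferase SHMT2 0.69 (SE 0.06). ATF4 itself was at 0.17 (SE 0.09) and not called.

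Of cholesterol biosynthesis genes 2 of 24 tested members were higher, 12 lower and 10 not called, 19 changed when adjusted over the list alone, and the median was -0.43 (camera adjusted p = 0.00250 with the preset correlation, and 0.916 with an estimated one). The sterol isomerase EBP fell from 173 ± 2.69 to 75.6 ± 1.87 CPM, the isopentenyl-diphosphate isomerase IDI1 from 175 ± 8.10 to 75.4 ± 4.82 CPM and the sterol oxidase MSMO1 from 133 ± 2.33 to 52.9 ± 7.47 CPM, with log2 fold changes of -1.20 (SE 0.06), -1.22 (SE 0.08) and -1.33 (SE 0.10), and FDPS, the farnesyl diphosphate synthase, had one of -0.73 (SE 0.06). Going the other way, HMGCS1, which makes HMG-CoA early in the pathway, rose by 0.76 (SE 0.11).

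With the preset correlation camera called 3 of the 32 lists, 1 higher and 2 lower. All 3 calls were lost with an estimated correlation (adjusted p = 0.916 each), and every one of the 10 splits of the 6 libraries into 3 and 3 called at least 3 lists. Splits that mix the labels keep part of their difference, so they cannot show what chance alone would call. With a library left out 2 lists were called without KO-labelled 1 or 2, and 7 without KO-labelled 3. Named members of the ATF4 and cholesterol lists that changed had adjusted p from 8.6e-06 to 0.00130 (edgeR quasi-likelihood test).

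**Figure D3:**
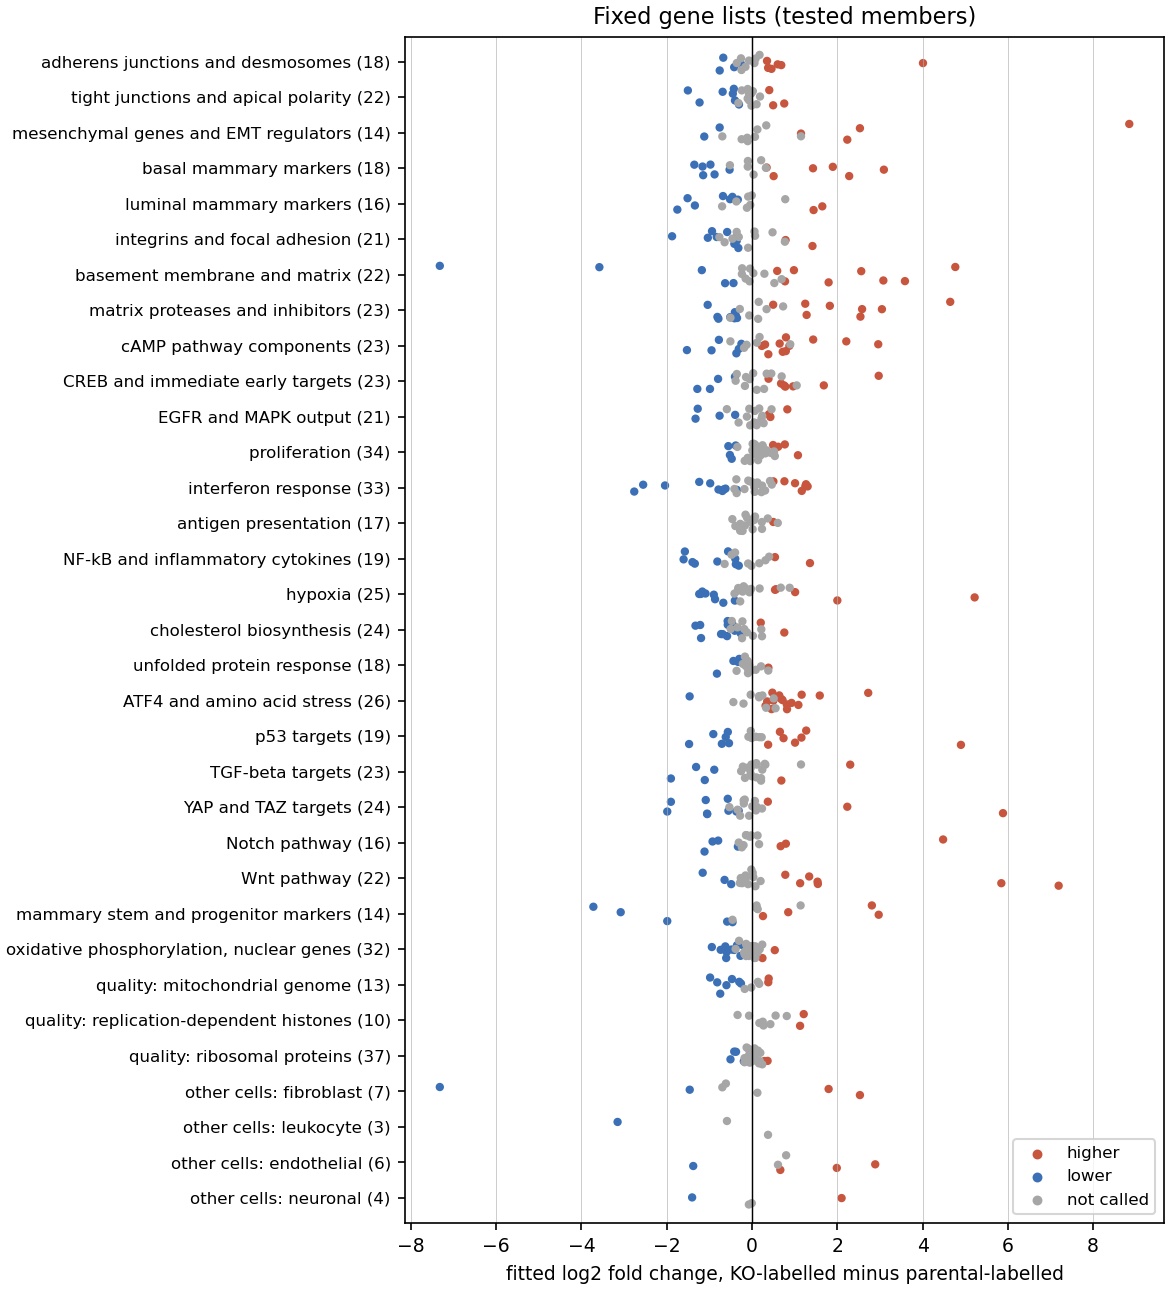
Fitted log2 fold change of each tested member (points, numbers of members in brackets) of 33 of the 34 fixed lists, KO-labelled minus parental-labelled, coloured by the edgeR call at an adjusted p of 0.05; vertical scatter within a list only separates the points. In the ATF4 list 16 members were higher and 1 lower and in the cholesterol list 2 and 12.

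Cell junction and adhesion lists moved in both directions. Among adherens junction and desmosome genes 6 of 18 tested members were higher, 4 lower and 8 not called (12 adjusted over the list alone; camera adjusted p = 0.921). The desmosomal plaque protein PKP1 rose by 4.01 (SE 0.45) on the log2 scale, P-cadherin (CDH3) fell from 117 ± 2.63 to 69.5 ± 8.91 CPM and PVRL2, which encodes nectin-2, had a log2 fold change of -0.67 (SE 0.09). E-cadherin (CDH1) had one of -0.42 (SE 0.07). For tight junctions and apical polarity 3 of 22 tested members were higher, 7 lower and 12 not called (10 adjusted over the list alone; camera 0.348). The polarity gene LLGL2 rose from 101 ± 8.94 to 171 ± 1.89 CPM, and the junction genes CLDN8 and CGN had log2 fold changes of -1.23 (SE 0.17) and -0.69 (SE 0.11). Of the integrin and focal adhesion genes 2 of 21 tested members were higher, 9 lower and 10 not called (12 adjusted over the list alone; camera 0.0621, 0.00688 without KO-labelled 3, and 0.916 with an estimated correlation and all libraries). Talin-1 (TLN1), which links integrins to actin, fell from 1197 ± 16 to 326 ± 13 CPM, vinculin (VCL) from 544 ± 12.4 to 307 ± 15 CPM and the kindlin FERMT2 from 91 ± 2.51 to 47.5 ± 3.82 CPM, whereas the laminin-binding integrin ITGB4 rose from 79.1 ± 3.51 to 211 ± 33.5 CPM.

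Matrix genes included some of the larger changes. In the basement membrane and matrix list 8 of 22 tested members were higher, 5 lower and 9 not called (13 adjusted over the list alone; camera 0.365). The type IV collagens COL4A1 and COL4A2, which are neighbouring genes, rose from 2.39 ± 0.476 to 65.9 ± 8.33 CPM and from 6.95 ± 0.237 to 58.8 ± 4.34 CPM, and the laminin chain LAMA4 from 16.5 ± 1.65 to 198 ± 20.8 CPM, while COL3A1 was 180.2-fold (95% counting interval 61.3 to 876) lower, with a fitted log2 fold change of -7.32, and -8.16 without KO-labelled 2. Of matrix proteases and inhibitors 8 of 23 tested members were higher, 8 lower and 7 not called (17 adjusted over the list alone; camera 0.748). Urokinase (PLAU) rose from 1.10 ± 0.177 to 27.7 ± 7.45 CPM, KLK10 had a log2 fold change of 2.58 (SE 0.21), and ADAM9 and KLK8 had ones of -0.79 (SE 0.08) and -1.04 (SE 0.10). Of mesenchymal genes and regulators of epithelial-mesenchymal transition 4 of 14 tested members were higher, 2 lower and 8 not called (6 adjusted over the list alone; camera 0.748). MMP2 rose from 1.14 ± 0.388 to 6.57 ± 2.03 CPM and LOXL2 fell from 84.6 ± 3.02 to 38.9 ± 13.5 CPM, while vimentin (VIM) at -0.70 (SE 0.46) and ZEB1 at 0.07 (SE 0.48) were not called, although without KO-labelled 3 VIM was called lower at -1.41 (edgeR adjusted p = 0.00425). Named genes of these 6 lists that changed had adjusted p from 1.3e-06 to 0.00405 (edgeR quasi-likelihood test).

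Markers of mammary cell identity split within each list. For basal markers 6 of 18 tested members were higher, 6 lower and 6 not called (12 adjusted over the list alone; camera 0.921). The keratins KRT15, KRT16 and KRT14 rose from 122 ± 6.10 to 328 ± 39.9 CPM, 62.8 ± 4.44 to 305 ± 117 CPM and 5.90 ± 0.260 to 21.9 ± 7.72 CPM, and the caveolin CAV2 had a log2 fold change of -0.88 (SE 0.12). EGFR was at 0.21 (SE 0.21) and not called. Of luminal markers 2 of 16 tested members were higher, 7 lower and 7 not called (9 adjusted over the list alone; camera 0.229). AGR2 rose from 25.6 ± 0.554 to 69.6 ± 6.31 CPM, while the mucin MUC1 fell from 291 ± 9.53 to 102 ± 12.7 CPM and the transcription factor XBP1 from 523 ± 2.05 to 206 ± 32 CPM. The oestrogen receptor gene ESR1 had a low level and a log2 fold change of -1.75 (SE 0.25), a call lost in the limma test on log2(FPKM + 1), with an adjusted p of 0.305. Among stem and progenitor markers 4 of 14 tested members were higher, 5 lower and 5 not called (9 adjusted over the list alone; camera 0.895). ID4 and BCL11A fell, with log2 fold changes of -3.08 (SE 0.10) and -3.72 (SE 0.37) (-4.44 for BCL11A without KO-labelled 1), and the aldehyde dehydrogenases ALDH1A1 and ALDH1A3 rose by 2.81 (SE 0.11) and 0.85 (SE 0.12).

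GPR52 couples to cAMP signalling, so genes of that pathway were a fixed list. There 11 of 23 tested members were higher, 6 lower and 6 not called (19 adjusted over the list alone; camera 0.348). The adenylyl cyclase ADCY7 rose from 6.22 ± 0.488 to 28.8 ± 7.03 CPM, and the regulatory protein kinase A subunit PRKAR2B fell from 65.5 ± 5.54 to 22.7 ± 3.59 CPM. The protein kinase A inhibitor PKIB had a log2 fold change of 2.96 (SE 0.32) at a low level, from 0.215 ± 0.0922 to 1.73 ± 0.296 CPM. Of CREB and immediate early targets 7 of 23 tested members were higher, 4 lower and 12 not called (12 adjusted over the list alone; camera 0.748). BTG2 rose by 1.68 (SE 0.16) and RGS2 had a log2 fold change of -1.28 (SE 0.13), while FOS at 0.03 (SE 0.18) and NR4A1 at 0.45 (SE 0.28) were not called, although without KO-labelled 3 NR4A1 was called higher at 0.71 (edgeR adjusted p = 0.00849). For output of EGFR and MAPK signalling 3 of 21 tested members were higher, 4 lower and 14 not called (7 adjusted over the list alone; camera 0.921). Cyclin D1 (CCND1) fell from 293 ± 8.16 to 121 ± 24.6 CPM and EMP1 had a log2 fold change of -0.76 (SE 0.10), while DUSP6 at -0.12 (SE 0.19) was not called. HBEGF at 0.83 (SE 0.17) and SPRY2 at 0.40 (SE 0.09) went the other way. The call of SPRY2 was lost without parental-labelled 3 (edgeR adjusted p = 0.0570). In the proliferation list 5 of 34 tested members were higher, 4 lower and 25 not called (8 adjusted over the list alone; camera 0.526). Survivin (BIRC5) rose from 107 ± 5.09 to 225 ± 52.3 CPM, the replication clamp PCNA had a log2 fold change of -0.52 (SE 0.09), and MKI67, at 0.54 (SE 0.20), was not called (edgeR adjusted p = 0.0629), but was called higher without KO-labelled 3, at 0.74 (edgeR adjusted p = 0.000201), with library totals (0.0485) and by DESeq2 (0.0225). Adjusted p of the changed genes named for the identity and signalling lists ran from 1.6e-06 to 0.0111 (edgeR quasi-likelihood test).

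Developmental pathway lists held single genes with large changes. Of Wnt pathway genes 7 of 22 tested members were higher, 3 lower and 12 not called (10 adjusted over the list alone; camera 0.705). The ligand WNT5A rose from 0.237 ± 0.122 to 34.5 ± 10.9 CPM, the receptor LGR6 from 0.198 ± 0.133 to 11.6 ± 1.54 CPM and the secreted antagonist DKK1 from 16.8 ± 0.995 to 36.8 ± 5.70 CPM. In the Notch list 3 of 16 tested members were higher, 4 lower and 9 not called (7 adjusted over the list alone; camera 0.822), with MAML3, a coactivator, at -0.79 (SE 0.14) and NOTCH2 at -0.33 (SE 0.07). Going the other way, LFNG, 1 of the 3 higher members, was at 0.79, and at 0.30 and not called relative to its neighbours. For TGF-beta targets 2 of 23 tested members were higher, 4 lower and 17 not called (6 adjusted over the list alone; camera 0.860). LTBP2 rose by 2.30 (SE 0.14), and the receptor TGFBR1 and the ligand TGFB2 fell from 89.4 ± 5.99 to 41.4 ± 3.20 CPM and from 152 ± 6.28 to 40.6 ± 16.1 CPM. Of YAP and TAZ targets 3 of 24 tested members were higher, 9 lower and 12 not called (12 adjusted over the list alone; camera 0.229, 0.0150 without KO-labelled 3, and 0.974 with an estimated correlation and all libraries). CYR61 fell from 153 ± 1.0 to 73.7 ± 12.1 CPM and ANKRD1 had a log2 fold change of -1.05 (SE 0.17), and the forkhead gene FOXF2 rose by 5.89 (SE 0.41). Without parental-labelled 1 FOXF2 was at 6.63, and LGR6 at 6.48 in place of 5.85.

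For p53 targets 7 of 19 tested members were higher, 6 lower and 6 not called (13 adjusted over the list alone; camera 0.748), with AEN at 1.16 (SE 0.07), TP53I3 at 1.27 (SE 0.11) and PHLDA3 at -0.91 (SE 0.11). Of hypoxia genes 5 of 25 tested members were higher, 8 lower and 12 not called (14 adjusted over the list alone; camera 0.477). The glycolytic enzyme PGK1 fell from 772 ± 6.79 to 327 ± 33.4 CPM and the oxygen sensor EGLN1 was at -0.90 (SE 0.07), whereas DDIT4 rose from 29.9 ± 0.825 to 119.7 ± 37.3 CPM. In the unfolded protein response list 1 of 18 tested members were higher, 5 lower and 12 not called (6 adjusted over the list alone; camera 0.321), with the chaperones HSP90B1 at -0.44 (SE 0.06) and DNAJB9 at -0.82 (SE 0.14). Of interferon response genes 7 of 33 tested members were higher, 10 lower and 16 not called (17 adjusted over the list alone; camera 0.894). MX1 fell from 52.2 ± 1.64 to 22.2 ± 5.15 CPM and GBP1 from 42 ± 1.73 to 10.2 ± 5.22 CPM, while HERC5 rose from 4.99 ± 0.601 to 12.3 ± 2.23 CPM. In the antigen presentation list 1 of 17 tested members were higher, 0 lower and 16 not called (1 adjusted over the list alone; camera 0.921), the change being ERAP1 at 0.50 (SE 0.08). For NF-kB targets and inflammatory cytokines 2 of 19 tested members were higher, 9 lower and 8 not called (11 adjusted over the list alone; camera 0.167, 0.00688 without KO-labelled 3, and 0.916 with an estimated correlation and all libraries). S100A7, also called psoriasin, fell from 495 ± 23.6 to 163 ± 44.6 CPM and the mitochondrial superoxide dismutase SOD2 from 143 ± 4.83 to 81.4 ± 9.68 CPM. The changed genes named for the developmental, stress and immune lists had adjusted p from 9.0e-06 to 0.00587 (edgeR quasi-likelihood test).

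Nuclear genes of oxidative phosphorylation fell more often than they rose. There 2 of 32 tested members were higher, 10 lower and 20 not called (12 adjusted over the list alone; camera 0.0590, 0.0456 without parental-labelled 2, 0.0150 without KO-labelled 3, and 0.916 with an estimated correlation and all libraries). The ATP synthase subunit ATP5C1 fell from 225 ± 1.33 to 117 ± 2.86 CPM, and UQCRFS1 of complex III had a log2 fold change of -0.63 (SE 0.06). Of the genes of the mitochondrial genome 2 of 13 tested members were higher, 7 lower and 4 not called (10 adjusted over the list alone; camera 0.229). MT-CO3 fell from 8623 ± 273 to 4898 ± 506 CPM and MT-CYB from 4096 ± 93.9 to 2443 ± 271 CPM, although the mitochondrial share of all counts was 7.37%, 7.75% and 7.68% in parental-labelled and 7.50%, 7.20% and 7.45% in KO-labelled libraries. For histone genes 2 of 10 tested members were higher, 0 lower and 8 not called (2 adjusted over the list alone; camera 0.365), with H1F0, a linker histone whose expression does not need replication, at 1.21 (SE 0.11). Of ribosomal protein genes 2 of 37 tested members were higher, 4 lower and 31 not called (5 adjusted over the list alone; camera 0.895), with RPS18 at -0.51 (SE 0.10) and RPS19 at -0.38 (SE 0.08). Mitochondrial, ribosomal and histone genes have near-identical copies elsewhere in the genome, so their counts are uncertain.

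Markers of other cell types were fixed lists too. In the fibroblast list 2 of 7 tested members were higher, 2 lower and 3 not called (4 adjusted over the list alone; camera 0.748). COL1A1 rose from 7.31 ± 0.881 to 25.5 ± 2.12 CPM and FBLN1 fell from 432 ± 34.5 to 157 ± 24.5 CPM, and COL3A1 and MMP2, given above, belong to this list too. For endothelial markers 3 of 6 tested members were higher, 1 lower and 2 not called (4 adjusted over the list alone; camera 0.321), with ESAM at 1.99 (SE 0.22) and CDH5 at -1.38 (SE 0.26). Among leukocyte markers 0 of 3 tested members were higher, 1 lower and 2 not called (1 adjusted over the list alone), the called member being CD14, which fell from 30.7 ± 5.38 to 3.45 ± 0.888 CPM. Of the neuronal genes 1 of 4 tested members were higher, 1 lower and 2 not called (2 adjusted over the list alone), and these last 2 lists had too few members for camera. The changed genes named here and for the mitochondrial, histone and ribosomal lists had adjusted p from 1.3e-06 to 0.00543 (edgeR quasi-likelihood test). A list's median, mean and camera direction did not share a sign for the adherens junction, basal, EGFR and MAPK, interferon, hypoxia, Notch, Wnt and stem cell lists. The directional fry test called 13 of the 32 lists and the mixed one 31, but neither compares a list with other genes.

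Neighbouring genes along chromosomes were compared next, because edited populations are derived cultures that can differ in copy number from the parent. On the X chromosome, 4 adjacent windows of 20 Mb from GYG2 to TAF9B were lower in KO-labelled libraries, with median log2 fold changes of -0.91, -1.0, -0.74 and -0.64, and 3 windows from TSPAN6 to TMLHE were higher, with 0.50, 0.45 and 0.54. Chromosome 2 had a window from LAPTM4A to THUMPD2 with a median of 0.55, in which the calls were 96 higher and 1 lower of 133 genes. The end of chromosome 17, from CCDC40 on, was higher at 0.74 (56 higher and 1 lower of 69), as was chromosome 15 from ZFAND6 to ADAMTS17 at 0.77 (64 higher and 4 lower of 95). Chromosome 9 from MLLT3 to CNTNAP3 was lower at -0.73 (13 higher and 59 lower of 111). The window that holds GPR52, on chromosome 1 from PIGM to CEP350, had a median of -0.37 (10 higher and 62 lower of 113).

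In all, 60 of 153 windows were called, 27 higher and 33 lower (camera, adjusted over windows), and in 57 of them all 3 KO-labelled libraries lay on one side of the parental-labelled mean. Whole chromosomes were called for 7 of 23, with chromosomes 17, 15 and 7 higher and 6, 21, 1 and 4 lower. With an estimated correlation, 5 windows and 5 chromosomes were called, and 3 of the 10 splits of the libraries gave as many windows as the real one, itself included. The other splits mix the labels and keep part of their difference, so that count does not measure chance alone. Part of the single-gene changes followed the windows. AKAP13, an anchoring protein for protein kinase A on chromosome 15, had a log2 fold change of 0.79 (SE 0.08) and 0.03 once the median of its window was taken off, and RABGAP1L went from -0.60 to -0.24, with its call lost (edgeR adjusted p = 0.0572). AEN, also on chromosome 15, went from 1.16 to 0.39. TLN1, in the chromosome 9 window, kept a value of -1.15, PGK1 on the X chromosome -0.60 and EBP -0.45. Of the other cholesterol genes, MSMO1 went from -1.33 to -0.82 and FDPS from -0.73 to -0.40, while IDI1 moved little, to -1.15. Among named genes in windows that were higher, LLGL2 went from 0.76 to 0.28, GARS from 0.82 to 0.40 and TP53I3 from 1.27 to 0.72. These cholesterol genes, LLGL2, GARS and TP53I3 kept their calls in the edgeR test. Of 6425 called genes that had a window, 4285 (66.7%) kept their call and direction relative to their neighbours. The same median was taken off all 3 KO-labelled libraries, although KO-labelled 3 did not share every window shift. Kept and lost calls therefore separate the effect of neighbours only in part. Over all called genes, 50 were called in the opposite direction relative to neighbours. Relative to neighbours, and with the preset correlation, the ATF4 and cholesterol lists were called and so were nuclear oxidative phosphorylation genes (camera adjusted p = 0.00106). With an estimated correlation no list was called relative to neighbours, and these 3 had adjusted p of 0.875, 0.874 and 0.874 (camera). The windows accounted for 7.71% of the variance of fitted log2 fold changes (adjusted R-squared) over the 14811 genes in windows, those with low counts included.

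**Figure D4:**
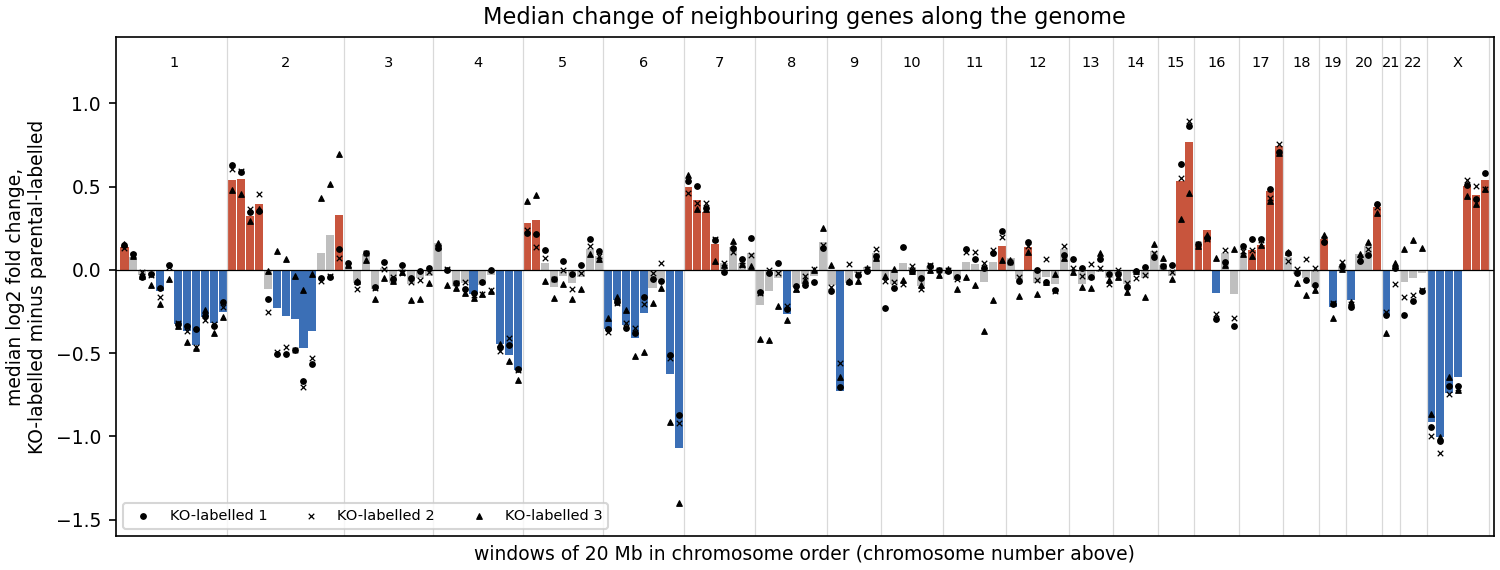
Median log2 fold change (bars) of the tested genes in each of 153 windows of 20 Mb, in chromosome order, KO-labelled minus parental-labelled; red and blue bars passed the camera test and grey bars did not, and the symbols give each KO-labelled library against the parental-labelled mean. The 4 windows of X from GYG2 to TAF9B lie below 0 in all 3 KO-labelled libraries and the 3 from TSPAN6 to TMLHE above 0.

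KO-labelled 3 shared most window shifts with KO-labelled 1 and 2 but not all. Window medians differed between KO-labelled 1 and 2 with an SD of 0.04 over the 153 windows, between 1 and 3 with 0.18 and between 2 and 3 with 0.17, against 0.02 to 0.05 within the parental-labelled group and 0.29 to 0.32 between groups. KO-labelled 1 and 2 were therefore as close by this measure as wells of the parental line, although their chi-square per gene of 13.9 was above the 3.08 to 5.72 of parental-labelled pairs. On chromosome 2 from ITGB6 to CWC22, for example, the medians were -0.67, -0.70 and -0.12 in KO-labelled 1, 2 and 3.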

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

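No paired analysis was possible because the labels give the 3 edited populations no replicate number that the parental wells share. Directions and calls of GPR52 held in every setting, with log2 fold changes from 3.66 (on log2(FPKM + 1), whose pseudocount shrinks low genes) to 10.12 (without parental 1). Between 4879 and 9367 genes changed with a library left out, the fewest without parental 2 and the most without KO-labelled 3, and 7835 without parental 1 and KO-labelled 3 together, a choice made after seeing the data, as were the values relative to neighbours and the switched-gene thresholds. Against a 1.5-fold change 1922 genes passed, 1019 higher and 903 lower, since that test asks for larger changes. Other settings gave 4935 (10 CPM filter, fewer genes tested) to 7132 genes (library totals), with DESeq2 at 7044 and limma voom at 7085. Higher genes were 51.5% of the calls, and 56.3% with upper quartile, 57.4% with library totals and 56.8% and 57.2% on FPKM. The main 3 called lists became 0 with an estimated correlation, as measured or relative to neighbours (the latter chosen after seeing the data), 13 and 31 with directional and mixed fry, which test another question, 5 without a filter (the cause was not tested), and 2 to 7 with a library left out, 2 without KO-labelled 1 or 2 and 7 without KO-labelled 3. Called windows fell from 60 to 5 with an estimated correlation, and were 56 to 62 with a library left out and 83 with windows of 10 Mb. The log2 ratio of the KO-labelled to the parental-labelled spread ranged from 0.40 (without KO-labelled 3) to 1.82 (without parental 3), against 1.12 with all libraries. Switched genes numbered 19 and 7 at 10 against 1 CPM, in place of 36 and 12 (both limits moved at once, so the cause was not tested). Of the comparisons of named genes with alternatives, 3074 kept the call, and the direction where called, 8 gained a call, 73 lost it (42 of them against a 1.5-fold change) and 2 reversed. The reversed genes were PDIA6 (0.38, and -0.15 relative to neighbours) and RPL38 (0.37, and -0.11), both in windows that were higher as a whole. Neither was called relative to neighbours.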

Other observations

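The tests of an exchange of labels, of the switched genes, of an inserted cassette and of trace counts were chosen only after the results were seen. In all, 48 genes, many of them named above, were switched between the groups, at 5 CPM or more in every library of one group and 0.5 CPM or less in every library of the other. There were 36 switched on in KO-labelled libraries and 12 in parental-labelled ones, and all 48 had an adjusted p under 0.05 in the edgeR quasi-likelihood test. Selection for such a gap in the same libraries makes a small p nearly certain, so it adds no support. Examples chosen from them after their values were seen are the neutral amino acid transporter SLC7A8 (0.0922 ± 0.0673 to 5.97 ± 1.03 CPM), the transcription factor ARNT2 (0.109 ± 0.116 to 13.2 ± 2.98 CPM), the RNA-binding protein CELF2 (0.0767 ± 0.106 to 9.09 ± 2.05 CPM), the immune surface molecule CD83 (0.343 ± 0.124 to 9.92 ± 1.79 CPM) and PRDM11 (0.408 ± 0.0739 to 12.6 ± 0.797 CPM), all higher in KO-labelled libraries (SD, n = 3 each). The fitted log2 fold changes of SLC7A8, ARNT2 and CELF2 were 5.95, 6.78 and 6.74, and 6.69, 7.83 and 8.67 without parental-labelled 1. Lower ones were RNF212, with 6.67 ± 0.662 CPM and 0 counts in the KO-labelled group, and ZIK1 (8.84 ± 0.374 to 0.313 ± 0.141 CPM). A stretch of chromosome 11 between MSANTD2 and EI24, chosen after its values were seen, held 10 genes with a known position, from ROBO3 to FEZ1. Together they had 53 counts in the parental-labelled and 4254 in the KO-labelled libraries, an 80.3-fold higher sum. Most of the KO-labelled counts came from ROBO3 (599), CCDC15 (1052), SLC37A2 (1054), TMEM218 (1036) and AP001007.1 (376). HEPACAM, FEZ1 and KRT18P59 had only 2, 5 and 12, so the sum does not describe every gene of the stretch. The bordering genes had 1320 against 1595 counts (MSANTD2) and 24545 against 21195 (EI24).

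Some genes set KO-labelled 3 apart from the other KO-labelled libraries and are given here as values without a test, with genes chosen after their values were seen. TGFBI, a matrix protein induced by TGF-beta, was at 17.6, 33.8 and 194 CPM in KO-labelled 1, 2 and 3, against 36.9 ± 1.89 CPM in parental-labelled libraries (SD, n = 3). NEDD9 was at 23.7, 30.8 and 105 CPM against 104 ± 4.26 CPM, and the stem cell marker PROM1 at 238, 180.3 and 46.7 CPM against 252 ± 9.68 CPM. EGFR, abundant in this cell line, was at 4560.4, 4927 and 8307 CPM against 5114 ± 220.3 CPM.

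The GPR52 transcript in libraries labelled GPR52 KO was weighed first. A complete exchange of the group labels would make the parental-labelled libraries the 3 separate populations. Instead the closest KO-labelled pair differed by 2.44 times the chi-square per gene of the widest parental-labelled pair, which argues against it as far as wells of a plate are closer to each other than edited populations are. KO-labelled 1 and 2 may be related, and that pair is the one compared. By the SD of window medians that pair, at 0.04, was within the range of parental-labelled pairs, 0.02 to 0.05. The pairs with KO-labelled 3 were wider, at 0.18 and 0.17, so by that measure only KO-labelled 3 argues against an exchange. GPR52 may be 1 member of a wider set of genes that differ in on or off state between the cultures, since 35 other genes were switched on in the same libraries. Transcription from an inserted editing cassette remains open, because RABGAP1L lay at percentile 23 of the log2 fold changes of its window, between the bounds of 5 and 25 set for the test, and an effect of the edit on the locus was not tested.

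The shifts of whole windows were weighed next. A trend on GC content and transcript length is argued against as their whole cause, since 44 of the 60 windows stayed called in the same direction once it was taken off each library. That correction was chosen after the data were seen. A difference in copy number or subclone between the cultures may underlie them, as medians of adjacent windows correlated with r = 0.784 across windows, which are not independent replicates (permutation p = 1e-04, the smallest the permutations can give). A DNA measurement was not analysed here, and the origin of the populations, the editing procedure and any effect of the edit cannot be separated in this design, because they go together with the label.

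The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Every split other than the real one has libraries of both labels on each side. It keeps part of the difference between the labels and adds that difference to the spread within sides. The splits therefore cannot show what would be called without a difference. For windows 3 of the 10 gave as many as the real 60, with 65 as the highest other. For genes 1 of 10 (the real split) gave 7105 in the edgeR test, with 0 as the highest other (65 to 380 genes per other split at an unadjusted p under 0.05), and for lists 10 of 10 gave the real 3 or more, with 12 as the highest other.

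Trace counts of genes high in KO-labelled libraries were seen in parental-labelled 1, at 0.937% of the KO-labelled level over 9 genes. The values were 0.253% and 0.179% over 7 genes each in parental-labelled 2 and 3. Genes were taken for each library by 0.5 CPM or less in the other 2 parental-labelled libraries, so the sets differ. FAR1 and VANGL2, with 21 counts each, were above that limit in parental-labelled 1. They are therefore in its set only and not among the switched genes, and its value rests partly on them. A small share of KO-labelled RNA or reads in that library could give such counts. The counts of the 9 genes departed from a uniform share, with a chi-square per degree of freedom of 2.84 (simulated p = 0.0052). PDZD4 had 0 counts where 8.94 would be needed, and VANGL2 had 21 where 11.5 would be. The KO-labelled populations differ among themselves in these genes, so a share of 1 of them, which was not tested, keeps this open, and it cannot be told apart from low expression in that well.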
